A study of Mus musculus with 24 samples.

How the data were processed

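RNA-seq libraries were made from bone marrow-derived macrophages of 12 male C57Bl/6 mice, 6 with streptozotocin-induced diabetes and 6 controls, each as 1 unstimulated and 1 stimulated culture, which gives 24 libraries in 4 groups of 6. RNA was extracted with a mirVana kit and libraries were made with a stranded mRNA kit, per the labels' protocols. Against these protocols, other labels give the material as genomic DNA; the data were treated as RNA-seq. STAR 2.5.3a, R 3.3.3 and edgeR 3.16.5, with the mouse builds GRCm38 and mm10, are named in the submitters' processing notes; the counting tool is not given in the sources used here. The authors deposited log2 CPM (counts scaled to library size) with a prior of 0.25 reads, scaled by an effective library size per library, for 13568 genes. Since every zero had the same value of -6.67, subtracting that floor on the linear scale gave CPM, and within 0.01 read 100% of the values in each library were whole reads. Read totals were 20098813 to 26572456 in unstimulated control, 16754771 to 28021162 in unstimulated diabetic, 22233139 to 34130060 in stimulated control and 23533465 to 29136332 in stimulated diabetic libraries. The implied scaling factors were 1.23 to 1.29 in unstimulated and 0.73 to 0.83 in stimulated libraries. Counting error and the floors given cover counting only, since reads without molecular identifiers are not independent molecules.

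The comparisons, the gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. That design allowed for CPM-like values or raw counts, and because the unit turned out to be log2, no count test was run. Genes with at least 1 CPM in at least 6 libraries (11710) were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with an intensity trend and robust empirical Bayes, in one model of the 4 group means with 20 residual degrees of freedom. The mean of both states was tested on 12 mouse means. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists with at least 3 tested members (34 of 38) were tested with limma's fry, which asks whether their genes move on balance one way, adjusted over the lists of a comparison; camera with an estimated correlation, which compares a list with other genes, was the alternative. The lists of T and NK cells, mast cells and granulocytes, fibroblasts and erythroid cells had fewer than 3 tested members and were not tested. Named genes were, per comparison, the 10 largest changes in each direction past the threshold, up to 4 members of each list with the smallest p, and a fixed panel of 10 genes, of which Arg1 was below the minimum level; 1 gene that this rule names is not reported here. Coordinates and gene names are those of the deposited table, and GC content and length are those of each gene's longest GENCODE transcript (GRCm38).

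The alternatives were other pseudocounts, filters, scalings, weights, fits, blocks and libraries left out, and their effect is given in the closing section. Libraries of a group correlated at r = 0.994 to 0.998, and a chi-square per degree of freedom of at least 2.96 between replicates showed no repeated library. The replicate number marks the same mouse within a phenotype, per the series' design text. Deviations from the group means of a mouse's 2 libraries correlated at a mean r of 0.18 (-0.08 to 0.46), above 0.1 in 9 of 12 mice. The columns of the table stand in 2 blocks of 12 libraries that hold 3 mice of each phenotype, and values within these blocks are given with the counts of genes, and for lists and genes where a block ended a call. The gene test and fry, in the model of group means, were run on simulated data with 200 changed genes. This covered the comparisons of phenotypes in each state and the interaction. It did not cover the mean of both states, the responses to stimulation, camera, voom or the fits with blocks. The simulated log2 changes were 0.5, 1, -0.5 and -1. In this order the gene test recovered 94%, 98%, 92% and 86% of the genes between phenotypes in unstimulated cells (11679 genes in the step). It recovered 94%, 98%, 88% and 94% in stimulated cells (11678 genes) and 76%, 94%, 78% and 88% for the interaction (11676 genes). Of all calls 6.42%, 7.31% and 6.63% were false in these comparisons. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.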

Results

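Bone marrow-derived macrophages are cells grown in culture from the bone marrow of a mouse under the growth factors that L929 cells release. Here the marrow came from 6 male C57Bl/6 mice made diabetic with streptozotocin, a toxin of the insulin-producing beta cells, and from 6 control mice. All cells were differentiated for 7 days and kept in medium with 5 mmol/L glucose, so that the cultures of both phenotypes saw the same glucose. Each sample was divided into an unstimulated culture and a culture stimulated for 6 h with 100 ng/mL lipopolysaccharide (LPS, a bacterial cell wall component sensed by TLR4) and 10 ng/mL interferon-gamma. This gave 4 groups of 6 RNA-seq libraries, with 1 unstimulated and 1 stimulated library per mouse. The libraries held between 16754771 and 34130060 reads in the 13568 listed genes, so a count of 3 reads corresponded to 0.0835 to 0.175 CPM (counts scaled to library size), and low genes were limited by counting error. Of the listed genes, 11710 reached the minimum level and were tested. Levels are given as mean CPM ± SD over 6 libraries, and fold changes as log2 differences of CPM + 1 with their SE. Adding 1 understates the change of low genes. Except in the mean of both states, SE and p-values rest on a spread shared by all 4 groups. They can be too large or too small for the groups compared where the spread of a gene differs between groups.

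**Figure D1:**
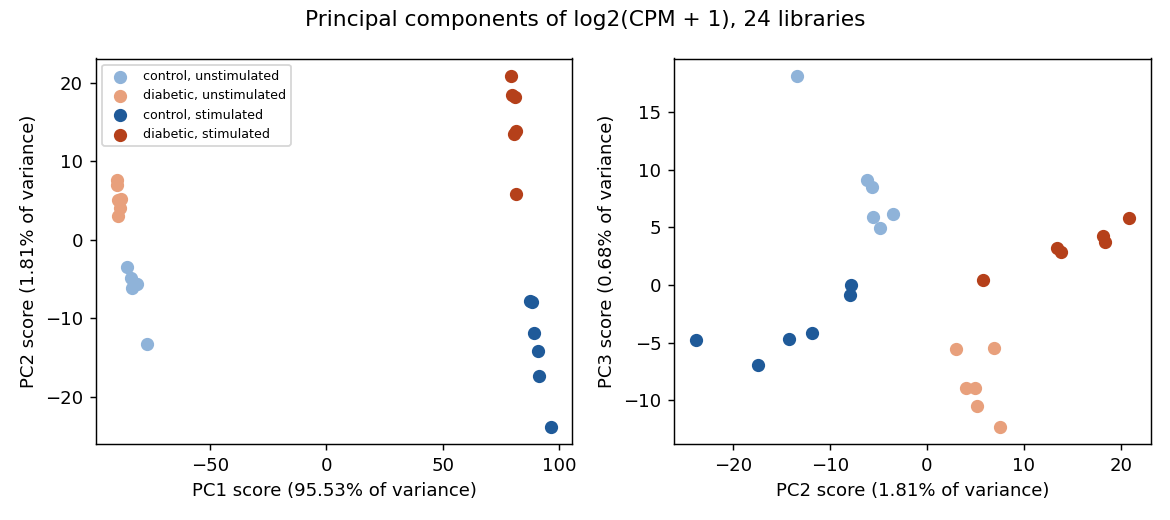
Principal component scores of the 24 libraries on log2(CPM + 1), with PC1 against PC2 on the left and PC2 against PC3 on the right; each point is 1 library and the axes give the percent of variance. PC1 (95.5% of the variance) parted stimulated from unstimulated libraries, and PC2 (1.81%) parted diabetic from control libraries in both states.

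The stimulus changed the cells of both phenotypes in much the same way. In control macrophages Nos2, the inducible nitric oxide synthase, went from 19.2 ± 7.80 to 12900 ± 974 CPM (log2 fold change 9.40 ± 0.16 SE, adjusted p = 2.0e-23). The chemokine gene Cxcl9 went from 9.75 ± 4.31 to 7267 ± 444 CPM (9.49 ± 0.17, adjusted p = 2.3e-23), and the cytokine gene Tnf from 38.6 ± 2.95 to 1230 ± 97.7 CPM (4.96 ± 0.05, adjusted p = 2.0e-33). All 17 tested inflammatory cytokines, all 22 type I interferon-stimulated genes, all 20 interferon-gamma-induced GTPases and regulators and all 16 M1-type activation markers rose, and so did 17 of 18 chemokines. All 18 genes listed as feedback inhibitors of NF-kB and TLR signalling rose, with Socs3 up by 8.43 and Nfkbia by 4.40 on the log2 scale. Of 20 glycolysis genes 17 rose, including Pfkfb3 (5.27 ± 0.05), whose product raises glycolytic flux. All 20 cell cycle genes and all 21 cholesterol synthesis and uptake genes fell. The replication helicase gene Mcm2 fell from 98.7 ± 5.53 to 5.54 ± 0.68 CPM, and Sqle, which encodes squalene epoxidase, fell from 91.5 ± 7.54 to 5.06 ± 0.91 CPM. The chemokine receptor gene Cxcr4 fell from 136 ± 5.94 to 1.26 ± 0.30 CPM (-5.93 ± 0.12, adjusted p = 3.2e-24). The same counts of changed members came with adjustment over each of these lists alone.

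In total 10688 of 11710 genes passed adjusted p < 0.05 in control cells, 4081 up and 6607 down, and 10574 in diabetic cells, 4117 up and 6457 down. Within the column blocks these counts were 10315 and 10165 in control and 10174 and 9986 in diabetic cells. The test of each list in one direction (fry) called 30 of 34 lists in control and 31 in diabetic cells. With an estimated correlation between genes 4 lists held in control cells, the cytokines (adjusted p = 0.019), chemokines (adjusted p = 0.023), M1-type markers (adjusted p = 0.030) and NF-kB inhibitors (adjusted p = 0.023). The split into higher and lower genes depended on the scaling. It was 5318 up and 5276 down in control cells and 5244 up and 5244 down in diabetic cells with median-of-ratios scaling, and 2300 up and 8856 down, and 2371 up and 8752 down, when scaled by total reads. These scalings moved the median of all genes by 0.30 and -0.62 in control cells and by 0.26 and -0.57 in diabetic cells, and quantile normalization moved it by 0.19 and 0.16. The directions of the lists for oxidative phosphorylation, the unfolded protein response, lipid handling, chromatin modifiers, macrophage identity, ribosomal proteins, mitochondrially encoded genes, NRF2 targets and M2-type markers turned with the scaling or with the set test in at least 1 phenotype, so no direction with stimulation is given for them. For the M2-type list the median and the test differed in sign, since 8 of 11 members fell in control cells (median -1.13) while fry gave a rise.

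Whether diabetes of the donor leaves a mark on macrophages grown in physiological glucose was addressed first in unstimulated cells. Interferon-stimulated genes were lower in macrophages from diabetic mice: all 22 listed type I interferon-stimulated genes fell, with a median log2 fold change of -1.19 (fry adjusted p = 6.9e-08; adjusted p = 0.095 with an estimated correlation). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481 in GRCm38), a transcription factor of the interferon response, was at 409 ± 170 CPM in control and 87.5 ± 25.1 CPM in diabetic libraries (-2.17 ± 0.19, adjusted p = 5.3e-08). Ifit3, an antiviral effector, was at 56.0 ± 23.8 and 14.2 ± 2.63 CPM (-1.85 ± 0.18, adjusted p = 1.9e-07), and Oasl2 at 325 ± 72.7 and 139 ± 18.7 CPM (-1.20 ± 0.10, adjusted p = 8.6e-09). In all 6 diabetic libraries the mean level of this list was below that of all 6 control libraries. Control mouse 3 had the highest level of the list, and without that mouse the median was -1.04. The columns of the table stand in 2 blocks of 12, which are possible batches. Restricted to libraries within column block 1 the median was -1.11 (fry adjusted p = 7.7e-06), and within column block 2 it was -1.27 (fry adjusted p = 0.0076).

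Other inflammatory genes were also lower in unstimulated diabetic cells. Of 20 interferon-gamma-induced GTPases and regulators 15 fell (16 fell and 1 rose adjusted over the list alone), with a fry adjusted p of 7.6e-06 and an adjusted p = 0.11 with an estimated correlation. Of 18 chemokines 8 fell (9 fell and 1 rose adjusted over the list alone; fry adjusted p = 2.5e-05; adjusted p = 0.11 with an estimated correlation), among them Ccl5, at 90.3 ± 41.6 and 26.7 ± 4.76 CPM (-1.64 ± 0.18, adjusted p = 7.0e-07). Of 17 cytokines 3 fell over all genes and over the list alone (fry adjusted p = 0.0090; adjusted p = 0.29 with an estimated correlation). Within the column blocks the cytokine list was not called (fry adjusted p = 0.10 in both). Tnf (-0.13 ± 0.05, adjusted p = 0.087) and Il6 (-0.28 ± 0.12, adjusted p = 0.10) did not pass the test. Il6 was at 0.55 to 1.36 CPM in control and 0.41 to 0.58 CPM in diabetic unstimulated libraries. Adding 1 therefore compressed its log2 fold change, which was -0.66 to -0.09 over the alternatives. Over the alternatives Tnf ranged from adjusted p = 0.0093 to 0.81 and passed without control library 3 or diabetic library 6, with array weights and within column block 1. Il6 ranged from 0.014 to 0.60 and passed with a pseudocount of 0.25, with array weights, on the deposited log2 values and in a fit of only the groups compared. Of 16 M1-type markers 5 fell over all genes and over the list alone (fry adjusted p = 0.0010; adjusted p = 0.23 with an estimated correlation), with fry adjusted p = 0.0092 and 0.16 in the column blocks. Of 17 macrophage identity genes 9 fell and 2 rose (12 fell and 2 rose adjusted over the list alone; fry adjusted p = 3.7e-05; adjusted p = 0.20 with an estimated correlation). The complement gene C1qa was at 637 ± 68.9 and 290 ± 24.7 CPM (-1.13 ± 0.09, adjusted p = 8.6e-09). The lipid carrier gene Apoe was at 1352 ± 151 and 643 ± 80.4 CPM (-1.07 ± 0.10, adjusted p = 5.9e-08). The GTPase, chemokine and macrophage identity lists were called within column block 1 (fry adjusted p = 0.00021, 0.0024 and 0.0018) and within column block 2 (fry adjusted p = 0.029, 0.024 and 0.047).

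Antioxidant, glycolytic and mitochondrially encoded genes were higher in unstimulated diabetic cells. Of 15 targets of NRF2, the transcription factor of the oxidative stress response, 11 rose (13 adjusted over the list alone), with a median of 0.40 (fry adjusted p = 3.1e-05; adjusted p = 0.11 with an estimated correlation). Nqo1, a quinone reductase, was at 4.37 ± 0.82 and 14.1 ± 4.81 CPM (1.45 ± 0.16, adjusted p = 2.6e-07), and Gclm, a subunit of the enzyme that starts glutathione synthesis, at 57.0 ± 4.03 and 105 ± 28.9 CPM (0.83 ± 0.13, adjusted p = 8.8e-05). Of 20 glycolysis genes 10 rose (12 adjusted over the list alone; fry adjusted p = 0.00014; adjusted p = 0.14 with an estimated correlation). The glucose transporter gene Slc2a1 was at 56.8 ± 4.78 and 81.3 ± 9.31 CPM (0.51 ± 0.06, adjusted p = 1.1e-06). Of 15 hypoxia response genes 8 rose over all genes and over the list alone (fry adjusted p = 0.00014; adjusted p = 0.11 with an estimated correlation). Of 21 cholesterol synthesis and uptake genes 11 rose (16 adjusted over the list alone; fry adjusted p = 0.0016; adjusted p = 0.22 with an estimated correlation), with fry adjusted p = 0.0082 and 0.10 in the column blocks. Of 20 cell cycle genes 12 rose and 3 fell (12 and 4 adjusted over the list alone; fry adjusted p = 0.0090; adjusted p = 0.32 with an estimated correlation), with fry adjusted p = 0.089 and 0.16 in the column blocks. Of 7 mitochondrially encoded genes 6 rose over all genes and over the list alone, with a median of 0.45 (fry adjusted p = 1.8e-06; adjusted p = 0.11 with an estimated correlation). The deposited table holds only 7 of the 13 genes on that list. All its genes whose symbol starts with mt- took 1.10% to 1.20% of the reads in diabetic and 0.79% to 0.94% in control libraries. None of the 25 oxidative phosphorylation genes encoded in the nucleus rose and 1 fell, over all genes and over the list alone, and the list was not called (fry adjusted p = 0.81). The NRF2, glycolysis, hypoxia and mitochondrially encoded lists were called within column block 1 (fry adjusted p = 0.0078, 0.0078, 0.0082 and 0.00094) and within column block 2 (fry adjusted p = 0.0076, 0.0076, 0.0076 and 0.012).

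Markers of other cells moved with the phenotype in part. Of 3 tested B lineage markers 1 rose and 1 fell over all genes and over the list alone, and the list was called (fry adjusted p = 0.028; adjusted p = 0.57 with an estimated correlation), but not within column block 2 (fry adjusted p = 0.30). Ighm, the constant region of the immunoglobulin M heavy chain, was at 11.6 ± 4.79 CPM in control and 36.7 ± 12.4 CPM in diabetic unstimulated libraries (1.60 ± 0.23, adjusted p = 2.4e-05). Restricted to libraries within column block 2 it did not pass the test (adjusted p = 0.071, the highest over its alternatives, which went down to 1.9e-06). Cd79b, which encodes a part of the B cell receptor, was at 1.42 ± 0.249 and 0.962 ± 0.279 CPM (-0.31 ± 0.10, adjusted p = 0.020). It did not pass in either column block or without unstimulated control library 2 or 3 or diabetic library 2, with an adjusted p of 0.0036 to 0.38 and a log2 fold change of -0.62 to -0.11 over the alternatives. Of 4 tested neutrophil markers Mmp8 (0.86 ± 0.10, adjusted p = 4.1e-07) and S100a8 (0.45 ± 0.07, adjusted p = 4.1e-05) rose (2 rose and 1 fell adjusted over the list alone), and the list was called (fry adjusted p = 3.2e-07; adjusted p = 0.11 with an estimated correlation). S100a8 was at 0.195 ± 0.0900 and 0.636 ± 0.113 CPM, so its fold change depended on the pseudocount (0.12 to 1.86 over the alternatives), and with a pseudocount of 5 it did not pass (adjusted p = 0.060, range 6.0e-07 to 0.060). Of 3 progenitor markers 1 rose over all genes and 2 over the list alone (fry adjusted p = 0.0016; adjusted p = 0.29 with an estimated correlation), and the list was not called within column block 1 (fry adjusted p = 0.20). Cd34 rose (0.57 ± 0.15, adjusted p = 0.0079), but did not pass on the deposited log2 values or within column block 1 (adjusted p = 0.29, with a range of 0.0018 to 0.29 over the alternatives, and of 0.26 to 0.87 in log2 fold change). Of 7 osteoclast markers 1 rose over all genes and 5 over the list alone (fry adjusted p = 0.011; adjusted p = 0.29 with an estimated correlation; fry adjusted p = 0.098 and 0.057 in the column blocks), and Ctsk, which encodes cathepsin K, had a log2 fold change of 1.35 ± 0.19 (adjusted p = 1.8e-05).

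Over all genes, 2265 of 11710 passed adjusted p < 0.05 between diabetic and control unstimulated cells, 1073 up and 1192 down, and 75 of them changed by at least 1 on the log2 scale, 16 up and 59 down. The count was 3502 with array weights, and 1506 and 861 within the 2 column blocks. Scaled by total reads the split was 1416 up and 939 down.

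**Figure D2:**
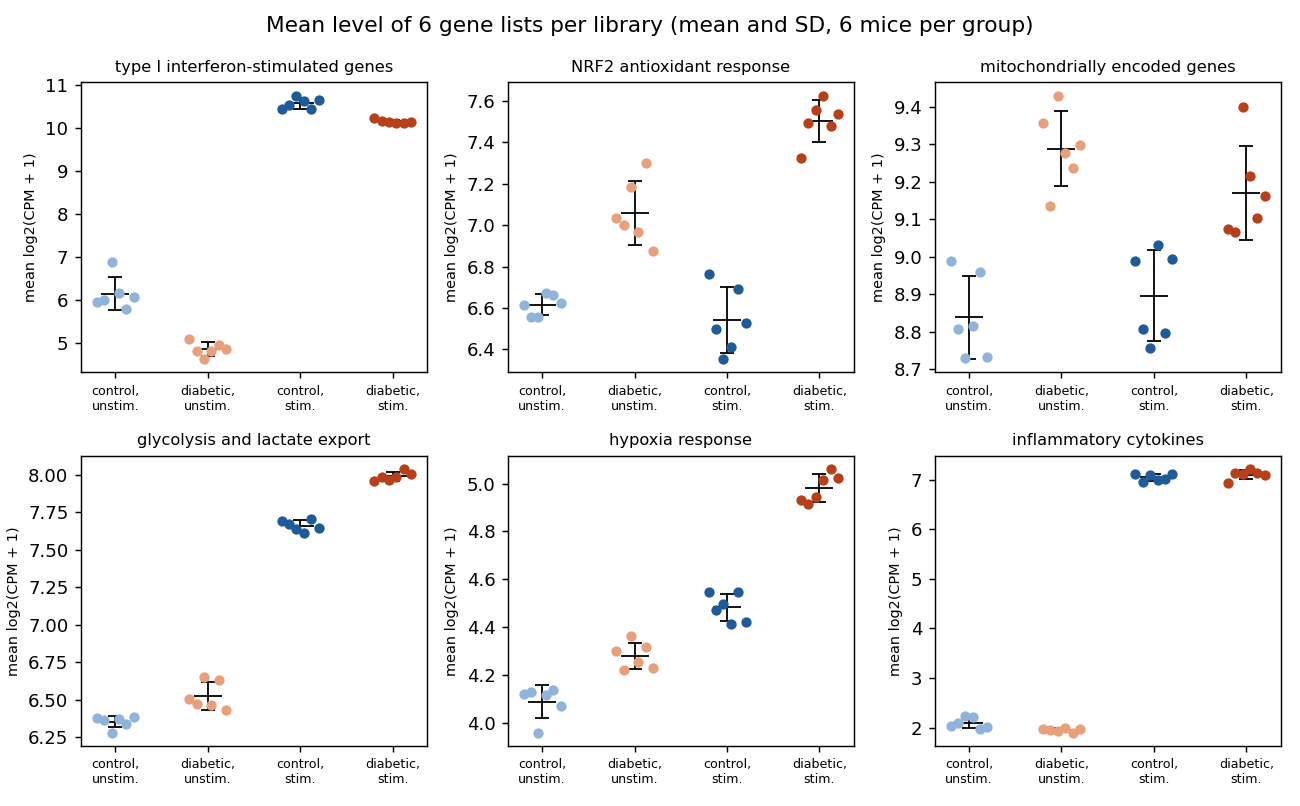
Mean log2(CPM + 1) over the tested members of 6 gene lists in each library (points), with the mean and SD over 6 mice per group (black bars); the vertical axes do not start at 0. The interferon-stimulated list was lower in all 6 diabetic libraries than in all 6 control libraries in both states, and the NRF2, mitochondrially encoded, glycolysis and hypoxia lists were higher.

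After stimulation, oxidative stress genes were higher in diabetic cells. Of 15 NRF2 targets 14 rose over all genes and over the list alone, with a median of 0.93 (fry adjusted p = 4.6e-10; adjusted p = 0.13 with an estimated correlation). Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589 in GRCm38), which encodes the heme-degrading enzyme heme oxygenase 1, was at 486 ± 80.6 CPM in control and 1682 ± 97.1 CPM in diabetic libraries (1.80 ± 0.11, adjusted p = 7.2e-11). Srxn1, which encodes sulfiredoxin, was at 43.1 ± 8.34 and 138 ± 16.97 CPM (1.67 ± 0.10, adjusted p = 7.2e-11). The scavenger receptor gene Marco was at 8.66 ± 3.32 and 60.9 ± 24.8 CPM (2.62 ± 0.25, adjusted p = 3.3e-08). Of 20 glycolysis genes 17 rose over all genes and over the list alone (fry adjusted p = 1.5e-08; adjusted p = 0.20 with an estimated correlation), among them Ldha (0.44 ± 0.05, adjusted p = 9.9e-08). Of 15 hypoxia response genes 12 rose over all genes and over the list alone (fry adjusted p = 1.6e-11; adjusted p = 0.10 with an estimated correlation). Of 7 mitochondrially encoded genes 6 rose over all genes and over the list alone (fry adjusted p = 6.5e-05; adjusted p = 0.58 with an estimated correlation). Within each column block these 4 lists were called, with NRF2 medians of 0.99 and 0.91.

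The cytokines of stimulated cells did not move one way. Of 17 tested cytokines 7 rose and 5 fell (7 and 6 adjusted over the list alone), and the list was not called (fry adjusted p = 0.76). Il12b, which encodes the shared p40 subunit of a pair of interleukins, was at 854 ± 199 CPM in control and 1682 ± 552 CPM in diabetic libraries (0.94 ± 0.20, adjusted p = 0.00061). Il1b was at 1779 ± 398 and 2726 ± 317 CPM (0.64 ± 0.13, adjusted p = 0.00031) and Il6 at 507 ± 67.7 and 738 ± 137 CPM (0.53 ± 0.12, adjusted p = 0.00057). Nos2 was at 12900 ± 974 and 18070 ± 1507 CPM (0.49 ± 0.16, adjusted p = 0.017), but did not pass the test in either column block (adjusted p = 0.16 in both) or with array weights. Its adjusted p ranged from 9.0e-06 to 0.16 over the alternatives. The SE of Nos2 also holds the spread of its unstimulated libraries, which in control was larger relative to the mean. Il12b did not pass within column block 1 (adjusted p = 0.057, with a range of 4.5e-05 to 0.057 over the alternatives). Tnf was at 1230 ± 97.7 and 1231 ± 63.8 CPM (0.00 ± 0.05, adjusted p = 0.96; 0.040 with quantile normalization, range over the alternatives 0.040 to 0.99), and Cxcl9 at 7267 ± 444 and 7658 ± 293 CPM (0.08 ± 0.17, adjusted p = 0.73). Il10, which encodes an anti-inflammatory cytokine, fell from 262 ± 35.3 in control to 135 ± 17.9 CPM in diabetic libraries (-0.95 ± 0.10, adjusted p = 4.0e-08). Of 18 chemokines 5 rose and 4 fell over all genes and over the list alone (fry adjusted p = 0.82), with Cxcl1 at 1.13 ± 0.14 and Cxcl11 at -0.80 ± 0.08.

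Interferon-related genes and the tested members of the feedback and M2-type lists were on balance lower in stimulated diabetic cells. Of 22 type I interferon-stimulated genes 17 fell over all genes and over the list alone, with a median of -0.39 (fry adjusted p = 0.0068, and 0.69 with an estimated correlation). In all 6 diabetic libraries the mean level of this list was below that of all 6 control libraries. The SD of that level was 0.12 in control and 0.045 in diabetic stimulated libraries, against 0.39 and 0.16 in unstimulated ones. The fry test drew its spread from all 4 groups. Restricted to libraries within column block 1 the list was called (fry adjusted p = 0.0016) and within column block 2 it was not (fry adjusted p = 0.25), with medians of -0.37 and -0.42, and with quantile normalization it was not called (fry adjusted p = 0.16). Ifit3 was at 1423 ± 196 and 693 ± 85.1 CPM (-1.03 ± 0.18, adjusted p = 5.4e-05). Of 11 tested M2-type markers 7 fell and 2 rose over all genes and over the list alone (fry adjusted p = 3.4e-09, and 0.10 with an estimated correlation). That list named 18 genes. Chil3, Retnla and Cd209a were absent from the deposited values and Arg1 was below the minimum level, so these markers could not be tested. Of 11 inflammasome genes 8 fell over all genes and over the list alone (fry adjusted p = 2.9e-08; adjusted p = 0.12 with an estimated correlation), among them Casp1 (-0.37 ± 0.05, adjusted p = 2.1e-07; -0.20 with quantile normalization). Of 18 genes listed as inhibitors of NF-kB and TLR signalling 14 fell and 1 rose over all genes and over the list alone (fry adjusted p = 1.7e-05, and 0.34 with an estimated correlation). With quantile normalization this list was not called (fry adjusted p = 0.051). Nfkbiz, whose product is not a plain inhibitor, fell (-0.73 ± 0.06, adjusted p = 4.3e-10) and Irak3 rose (0.53 ± 0.05, adjusted p = 1.4e-08). No direction of NF-kB activity is read from this list. Pparg, a lipid-sensing nuclear receptor, was at 8.32 ± 2.12 and 2.62 ± 0.62 CPM (-1.36 ± 0.11, adjusted p = 5.0e-10; -1.67 to -0.80 over the alternatives), and Apoe at 1283 ± 126 and 526 ± 90.6 CPM (-1.30 ± 0.10, adjusted p = 1.1e-09). Of 29 chromatin modifiers 7 rose and 10 fell (7 and 11 adjusted over the list alone; fry adjusted p = 0.66), with Setd7, a histone methyltransferase gene, at 0.68 ± 0.07 (adjusted p = 1.5e-08; 0.45 to 0.78 over the alternatives). Ighm was again higher in diabetic libraries (1.03 ± 0.23, adjusted p = 0.00075; adjusted p = 0.11 within column block 2, range over the alternatives 1.8e-05 to 0.11), and did not pass with voom either. Its log2 fold change was 0.45 to 1.58 over the alternatives.

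Over all genes, 6059 of 11710 passed the test in stimulated cells, 3494 up and 2565 down, and 105 of them changed by at least 1 on the log2 scale, 51 up and 54 down. The split was 2717 up and 3425 down with median-of-ratios scaling and 5213 up and 1528 down when scaled by total reads. The counts within the column blocks were 4187 and 4406. Among genes called in both states, 518 were higher and 693 lower in diabetic cells in each (320 and 261 in independent lists of these sizes), and 232 had opposite signs (591 in independent lists). These comparisons share mice but no libraries.

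**Figure D3:**
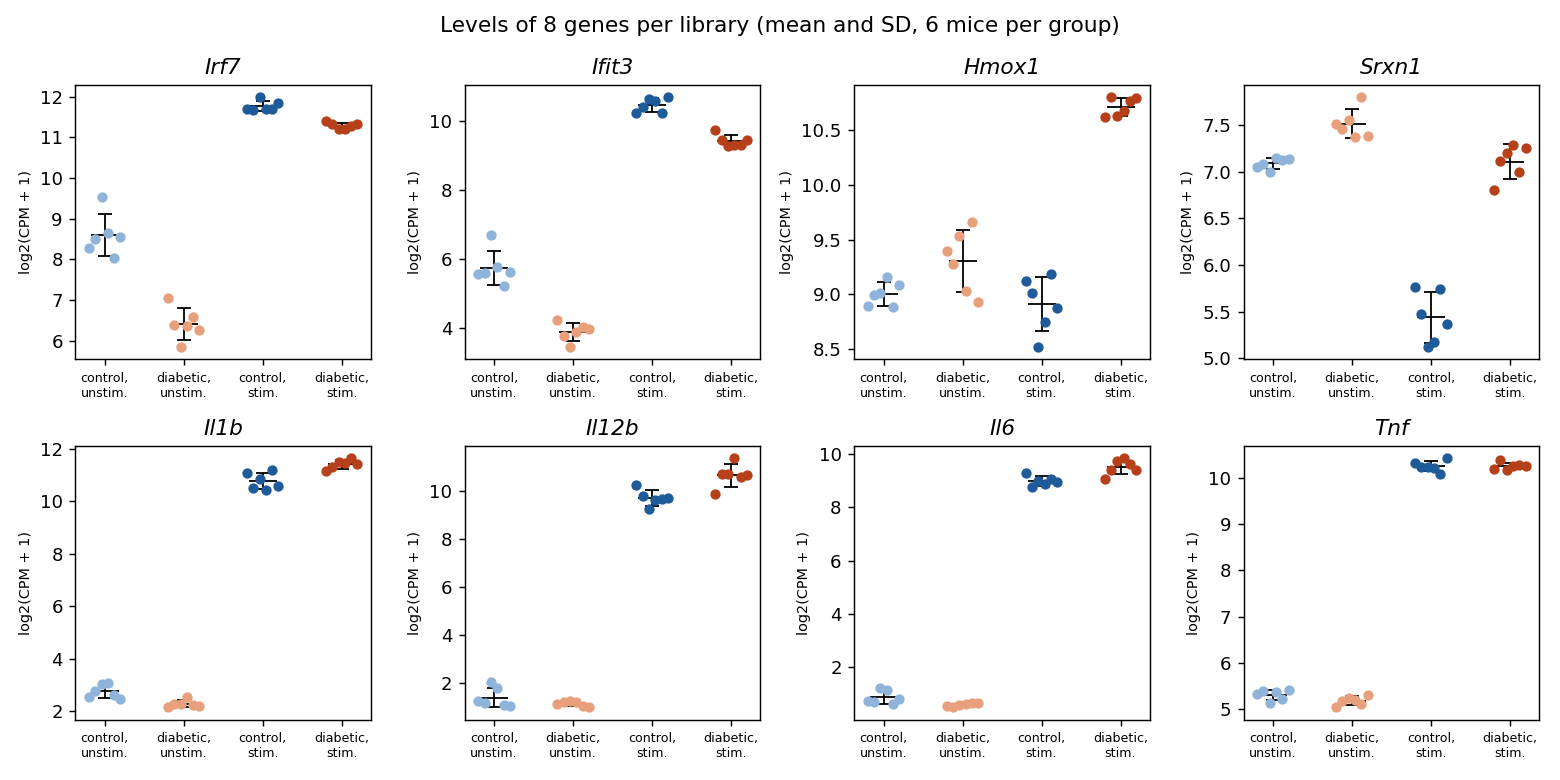
Levels of 8 genes as log2(CPM + 1) in each library (points), with the mean and SD over 6 mice per group (black bars); the vertical axes do not start at 0. Irf7 and Ifit3 were lower in diabetic libraries in both states, Hmox1 was higher in diabetic libraries after stimulation, and stimulated Tnf was at 1230 CPM in control and 1231 CPM in diabetic libraries.

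The last question was whether the response to the stimulus itself differed between phenotypes. The log2 responses of the 2 phenotypes correlated at r = 0.985 across genes, which are not independent replicates, and 99.2% of the genes called in both had the same sign. The difference of the responses (the interaction) passed the test for 3747 genes, 2297 positive and 1450 negative, and 78 of them reached 1 on the log2 scale, 48 positive and 30 negative. Of the 3747 genes 3231 also passed the test of the response in both phenotypes with the same sign. Among these, 800 rose less and 1487 fell less in diabetic than in control cells, while 488 rose more and 456 fell more. With median-of-ratios scaling 1278 rose less and 488 more, and 1011 fell less and 506 more. With scaling by total reads 418 rose less and 450 more, and 2541 fell less and 477 more. Type I interferon-stimulated genes rose more in diabetic cells, from their lower start: 20 of 22 had a positive interaction over all genes and over the list alone, with a median of 0.78 (fry adjusted p = 0.00085; adjusted p = 0.80 with an estimated correlation). Of 15 NRF2 targets 9 had a positive and 1 a negative interaction (10 and 1 adjusted over the list alone; fry adjusted p = 0.00085; adjusted p = 0.85 with an estimated correlation). Hmox1 had an interaction of 1.503 ± 0.16 (adjusted p = 5.2e-07), with a log2 change on stimulation of -0.09 in control cells (adjusted p = 0.41) and 1.41 in diabetic cells (adjusted p = 1.4e-11). Of 15 hypoxia response genes 8 were positive (9 and 1 negative adjusted over the list alone; fry adjusted p = 6.9e-06; adjusted p = 0.43 with an estimated correlation). Of 18 chemokines 10 were positive and 2 negative over all genes and over the list alone (fry adjusted p = 0.0027; adjusted p = 0.85 with an estimated correlation). Of 11 M2-type markers 6 were negative and 1 positive (6 and 2 adjusted over the list alone; fry adjusted p = 1.2e-05; adjusted p = 0.23 with an estimated correlation). Restricted to libraries within column block 1 the interferon-stimulated, NRF2 and chemokine lists were called (fry adjusted p = 0.00079, 0.0014 and 0.019), and within column block 2 they were not (fry adjusted p = 0.18, 0.31 and 0.15). The hypoxia and M2-type lists were called in both. Of 16 M1-type markers 7 were positive and 1 negative (8 and 1 adjusted over the list alone; fry adjusted p = 0.0044; adjusted p = 0.85 with an estimated correlation). Of 20 glycolysis genes 9 were positive over all genes and over the list alone (fry adjusted p = 0.013; adjusted p = 0.98 with an estimated correlation), and with median-of-ratios scaling the list was not called (fry adjusted p = 0.083). Of 11 inflammasome genes 4 were negative (5 adjusted over the list alone; fry adjusted p = 0.0044; adjusted p = 0.80 with an estimated correlation), and with quantile normalization the list was not called (fry adjusted p = 0.076). Of these 3 lists none was called within column block 2 (fry adjusted p = 0.19, 0.72 and 0.37).

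Among cytokine genes and Nos2 the interaction was 1.11 ± 0.18 for Il1b (adjusted p = 0.00010), 1.20 ± 0.29 for Il12b (adjusted p = 0.0031), 0.81 ± 0.16 for Il6 (adjusted p = 0.00065) and 0.76 ± 0.23 for Nos2 (adjusted p = 0.015). Unstimulated Il6 (0.41 to 1.36 CPM) and Il12b (1.03 to 3.10 CPM) were so low that adding 1 weighed on their responses. Their interactions were 0.61 to 1.19 and 0.94 to 1.47 over the alternatives. With voom on the recovered reads Il12b (adjusted p = 0.15, range over the alternatives 0.00035 to 0.15) and Il6 (adjusted p = 0.11, range 5.5e-05 to 0.11) did not pass. Within the column blocks Il12b (adjusted p = 0.10 and 0.069) and Nos2 (adjusted p = 0.16 and 0.17, range over the alternatives 0.0059 to 0.17) did not pass in either, nor Nos2 with array weights. Tnf (0.14 ± 0.08, adjusted p = 0.17) and Cxcl9 (0.43 ± 0.23, adjusted p = 0.17) did not pass. Tnf passed with quantile normalization (adjusted p = 0.0090), scaled by total reads (adjusted p = 0.025) and with array weights, with a range of 0.0090 to 0.68 over the alternatives. Marco, at 2.62 ± 0.35 (adjusted p = 1.4e-05), did not pass with voom (adjusted p = 0.066, range over the alternatives 1.9e-07 to 0.066). Myc fell further in diabetic cells (-1.01 ± 0.12, adjusted p = 8.2e-07; -1.18 to -0.66 over the alternatives), as did Pparg (-1.05 ± 0.15, adjusted p = 1.2e-05; -1.36 to -0.52), and both were weakest with a pseudocount of 5. The interaction count was 2440 and 1642 within the column blocks, and its split was 1765 positive and 2032 negative with median-of-ratios scaling and 3208 and 1018 when scaled by total reads.

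Averaged over both states, 5229 genes differed between diabetic and control cells, 2846 up and 2383 down. All 15 NRF2 targets rose and all 22 interferon-stimulated genes fell over all genes and over the list alone, with fry adjusted p = 1.0e-06 and 4.7e-05 (adjusted p = 0.20 and 0.26 with an estimated correlation). Siglec1, an interferon-inducible sialic acid receptor gene, had a mean difference of -1.45 ± 0.19 (adjusted p = 0.00013) and Nqo1 of 1.30 ± 0.09 (adjusted p = 3.1e-07; 0.80 to 1.58 over the alternatives). Both lists were called within column block 1 (fry adjusted p = 0.00029 and 0.0013) and within column block 2 (fry adjusted p = 0.0070 and 0.041). The count was 3386 and 3091 within the column blocks. The split was 2287 up and 2965 down with median-of-ratios scaling and 4640 up and 1501 down when scaled by total reads.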

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

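The tests of exposure to the stimulus, of the authors' normalization, of control mouse 3 alone, of a proportionally smaller response, of respiratory chain transcripts, of the column blocks, with voom and on the deposited log2 values were chosen only after the result was seen.

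Control mouse 3 stood apart among the 6 unstimulated control libraries in 5 of the values checked. In its library Ifit3 was at 103 CPM (36.8 to 53.7 in the others), Oasl2 at 468 CPM (262 to 316) and Slc2a1 at 47.8 CPM (56.8 to 62.1). Its mean log2 level was 6.90 for the type I interferon-stimulated list (5.80 to 6.18 in the others) and 3.96 for the hypoxia list (4.07 to 4.14). Pparg was at 12.4 CPM in the stimulated library of the same mouse (6.48 to 8.06 in the others). Nos2 was at 14748 CPM in stimulated control mouse 1 (11929 to 12842), and Mcm2 at 109.5 CPM in unstimulated control mouse 6 (94.9 to 99.4). Of 92 groups of libraries checked 8 held such a library, where chance gives about 1 in 20, or 4.6.

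The response to stimulation differed between phenotypes, by the test of the interaction, for 3747 genes. Of these, 713 also differed between phenotypes in unstimulated cells with the opposite sign (367 in independent lists). Both comparisons use the same unstimulated libraries, so they are not independent. All 22 type I interferon-stimulated genes, with Irf7, Oasl2 and Mx1 among them, started lower in unstimulated diabetic cells. Among the genes named, the difference of diabetic minus control was 2.62 for Marco, 1.503 for Hmox1, 1.24 for Srxn1, 1.10 for Gclc, 1.69 for Irf7, 1.01 for Oasl2 and 1.41 for Mx1 on the log2 scale. It was 1.11 for Il1b, 1.20 for Il12b, 0.81 for Il6, 0.76 for Nos2, 0.51 for Ccl2, 1.45 for Ccl5, 1.08 for Cxcl3 and -0.75 for Cxcl11, whose annotation is a polymorphic pseudogene. It was 1.70 for Saa3, 1.73 for Thbs4, 1.56 for Ampd3, -1.71 for Rilpl1, -1.55 for Rgs1, -1.01 for Myc, -1.05 for Pparg and -1.30 for Egr2. For Adm the fitted difference was 0.97 (0.39 to 2.26 over the alternatives). It depends on the pseudocount, since all 6 unstimulated diabetic libraries were at 0 CPM. The median difference was 0.78 for the type I interferon-stimulated list, 0.52 for NRF2, 0.43 for chemokines, 0.37 for M1-type markers, 0.35 for hypoxia, 0.17 for glycolysis, -0.13 for the inflammasome and -0.40 for M2-type markers. With an estimated correlation the adjusted p of these lists was 0.80, 0.85, 0.85, 0.85, 0.43, 0.98, 0.80 and 0.23 in this order, and within column block 2 of them only hypoxia and M2-type markers were called. Ccl2 lost its call when any 1 of unstimulated control libraries 1, 2 or 6, stimulated control libraries 1 or 5 or stimulated diabetic library 6 was left out. Within the column blocks Nos2, Il12b and Ccl2 lost it in both, and Ccl5 and Egr2 in block 2. Ccl2 also lost it with median-of-ratios scaling and Nos2 with array weights. With voom on the recovered reads Il12b, Il6, Marco, Egr2, Thbs4, Cxcl3 and Cxcl11 lost it, and Cxcl3 and Cxcl11 also on the deposited log2 values. The adjusted p reached 0.59 for Cxcl3 (log2 0.46 to 1.22 over the alternatives), 0.49 for Cxcl11 (-0.82 to -0.51) and 0.11 for Thbs4 (1.12 to 2.23).

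Chance alone is unlikely for each count, since of the splits examined only 1, the real one, called as many genes. The splits cannot tell diabetes from a batch that follows the phenotype. Of 100 splits the real one called 2265 genes between phenotypes in unstimulated cells (at most 783 in the others), 6059 in stimulated cells (4127), 3747 in the interaction (144) and 5229 in the mean of both states (1183). It called 10688 genes in control and 10574 in diabetic cells with stimulation (9653 and 9498 in the other splits). Of 32 splits that parted all 6 pairs of a mouse's libraries, the highest of the others called 9621 and 9493 (any split outside these 32 puts both libraries of at least 1 mouse on the same side). A split of the 12 mice by column block called 5 genes in the mean of both states.

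Interferon-stimulated genes were lower in unstimulated diabetic cultures (median -1.19). Traces of the stimulus in the control cultures cannot be told apart. The 24 cytokine and NF-kB genes tested, induced by it and at 5 CPM or more, had a median of -0.18 (quartiles -0.24 and -0.07). They leave out the interferon-gamma-induced list and the chemokines, which the stimulus also raised and whose medians were -0.47 and -0.31. The authors' normalization is argued against by the weakest median under 3 other scalings, -1.17, and control mouse 3 alone by the median without it, -1.04. Diabetes of the donor, which the design cannot part from the streptozotocin that induced it, stays open as a biological explanation and was not tested further. Cages, litters and culture days are not given in the sources used here, so a batch that follows the phenotype cannot be told apart from it.

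NRF2 target genes were higher in stimulated diabetic cultures (median 0.93). After removal of the trend with GC content, transcript length and mean level over 11702 genes, which took 6.67% of the variance, the median was 1.04. A proportionally smaller response of all genes predicted a median interaction of 0.0113 against 0.52 observed. The slope of the diabetic on the control response was 0.97, and in control cells 6 members rose and 8 fell. The prediction could therefore only be near 0, and no conclusion is drawn from it. The weakest median under 3 other scalings was 0.88. Diabetes of the donor, which the design cannot part from streptozotocin and which was not tested further, and a batch that follows the phenotype stay open.

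Mitochondrially encoded transcripts were higher in unstimulated diabetic cultures (median 0.45). The authors' normalization is argued against by the weakest median under 3 other scalings, also 0.45, and a general rise of respiratory chain transcripts by the upper quartile of the list encoded in the nucleus, 0.04. Loss of cytoplasmic RNA from damaged cells cannot be told apart, since the nuclear RNA Malat1 had a log2 fold change of 0.16 ± 0.21 SE and Neat1 of 0.10 ± 0.09. Diabetes of the donor, which the design cannot part from streptozotocin, and a batch that follows the phenotype stay open and were not tested.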

How the results depend on the processing

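The tests within column blocks, with a column-block term, with total-read scaling, with voom, on the deposited log2 values and without control mouse 3, and the other scalings of the gene lists, were chosen after the data were seen. A count test on whole reads (edgeR or DESeq2) had been planned and was not run, because the deposited unit is log2; voom on the recovered reads was used in its place. Of 7292 comparisons of a named gene with an alternative, 7135 kept direction and side of the threshold, 19 gained the call, 138 lost it and 0 reversed; of these losses 70 came from asking for an absolute log2 fold change of at least 1. Of 1530 such comparisons of gene lists, 1239 kept both, 62 gained, 196 lost and 33 reversed. Pseudocounts of 0.25 and 5, no filter, a stricter filter, fits of only the groups compared, the library-number quartet term and the column-block term kept all counts of genes within 1.5 times. Leaving out 1 library gave 1847 to 2395 genes between phenotypes in unstimulated cells, 5545 to 6170 in stimulated cells, 10617 to 10703 and 10495 to 10607 in the responses of control and diabetic cells and 3445 to 4003 in the interaction, and leaving out 1 mouse gave 4720 to 5234 in the mean of both states. A pseudocount of 5 moved 19 called log2 fold changes of named genes by over 1.5 times, and leaving out 1 library or mouse moved 0. Depth limited low genes, since 3 reads in 1 library were 0.0835 to 0.175 CPM. Where a call changed below, the cause was not tested, except that the column blocks hold fewer libraries.

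With the mouse as replicate block, the pairing of each mouse's libraries gave 10718 and 10596 genes in the responses of control and diabetic cells and 3925 in the interaction. The block ended the call of macrophage identity in both responses (adjusted p = 0.075 and 0.21) and gave one to mitochondrially encoded genes in diabetic cells (0.0061); among the other lists it gave a call to neutrophil (0.044) and endothelial markers (0.043) in the interaction and to the sex check genes in the responses of control (0.0066) and diabetic cells (0.0069). Across phenotypes the replicate number showed no pairing on average. Same-numbered libraries correlated at a mean r of 0.0083 unstimulated (-0.25 to 0.29) and 0.020 stimulated (-0.33 to 0.24). Number 5 was its own best match in unstimulated libraries, and numbers 2 and 5 were in stimulated libraries. Number 2 (r = 0.29 and 0.22) and number 5 (0.28 and 0.24) were positive in both states, and number 1 was negative in both (-0.25 and -0.33).

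The larger fold threshold left 75 genes between phenotypes in unstimulated and 105 in stimulated cells, 5022 and 4640 in the responses, 78 in the interaction and 46 in the mean of both states. Array weights gave 3502 in unstimulated cells. Column block 1 gave 1506 in unstimulated cells, 2440 in the interaction and 3386 in the mean, and column block 2 gave 861, 1642 and 3091. The number of lists called went from 19, 20, 8 and 21 to 0 in each of the comparisons of phenotypes, and from 30 and 31 to 4 and 4 in the responses, with camera and an estimated correlation, which sets a list against other genes. It was 11, 12, 2 and 13 in column block 2 and 13 in the interaction with quantile normalization.

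The numbers after list names are Benjamini-Hochberg adjusted p-values. The lists of other-cell markers and sex check genes are given in the last paragraph. With camera and an estimated correlation these calls of the remaining lists were lost. Between phenotypes in unstimulated cells they were cytokines 0.29, chemokines 0.11, type I interferon 0.095, GTPases 0.11, M1-type 0.23, TLR 0.22, NF-kB inhibitors 0.22, inflammasome 0.24, glycolysis 0.14, cholesterol 0.22, hypoxia 0.11, NRF2 0.11, cell cycle 0.32, macrophage identity 0.20 and mitochondrially encoded 0.11. Between phenotypes in stimulated cells they were type I interferon 0.69, GTPases 0.58, MHC II 0.88, M2-type 0.10, TLR 0.40, NF-kB inhibitors 0.34, inflammasome 0.12, glycolysis 0.20, fatty acid oxidation 0.88, hypoxia 0.10, NRF2 0.13, insulin 0.88, cell cycle 0.78, macrophage identity 0.58 and mitochondrially encoded 0.58. In the response of control cells they were type I interferon 0.24, GTPases 0.12, MHC II 0.36, TLR 0.18, inflammasome 0.18, glycolysis 0.18, oxidative phosphorylation 0.80, TCA cycle 0.59, fatty acid oxidation 0.80, cholesterol 0.37, hypoxia 0.46, unfolded protein 0.95, NADPH oxidase 0.12, insulin 0.48, cell cycle 0.23, immediate early 0.28 and ribosomal proteins 0.97. In the response of diabetic cells they were type I interferon 0.22, GTPases 0.11, MHC II 0.30, TLR 0.21, inflammasome 0.22, glycolysis 0.17, oxidative phosphorylation 0.80, TCA cycle 0.63, fatty acid oxidation 0.82, cholesterol 0.29, hypoxia 0.29, unfolded protein 0.97, NRF2 0.82, NADPH oxidase 0.11, insulin 0.35, cell cycle 0.22, immediate early 0.29 and ribosomal proteins 0.97. In the interaction they were chemokines 0.85, type I interferon 0.80, M1-type 0.85, M2-type 0.23, inflammasome 0.80, glycolysis 0.98, hypoxia 0.43 and NRF2 0.85. In the mean of both states they were chemokines 0.44, type I interferon 0.26, GTPases 0.27, M2-type 0.26, TLR 0.27, NF-kB inhibitors 0.20, inflammasome 0.20, glycolysis 0.20, fatty acid oxidation 0.64, cholesterol 0.64, hypoxia 0.20, NRF2 0.20, insulin 0.64, cell cycle 0.57, macrophage identity 0.29 and mitochondrially encoded 0.27. Camera gave the opposite direction in the response of control cells for M2-type 0.95, chromatin 0.83 and macrophage identity 0.95, and in the response of diabetic cells for M2-type 0.80, chromatin 0.90 and macrophage identity 0.97.

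Restriction to column block 1 ended calls between phenotypes in unstimulated cells for cytokines 0.10 and cell cycle 0.089, and between phenotypes in stimulated cells for MHC II 0.18, insulin 0.058 and cell cycle 0.062. It also ended calls in the response of control cells for oxidative phosphorylation 0.052, and in the response of diabetic cells for macrophage identity 0.45. It also ended calls in the mean of both states for insulin 0.18 and cell cycle 0.075. Restriction to column block 1 gave new calls in the response of diabetic cells for mitochondrially encoded 0.034, and in the interaction for fatty acid oxidation 0.00025 and cholesterol 0.021. It also gave calls in the mean of both states for M1-type 0.048. Restriction to column block 2 ended calls between phenotypes in unstimulated cells for cytokines 0.10, M1-type 0.16, TLR 0.057, inflammasome 0.11, cholesterol 0.10 and cell cycle 0.16, and between phenotypes in stimulated cells for type I interferon 0.25, GTPases 0.084, MHC II 0.12, fatty acid oxidation 0.15 and cell cycle 0.055. It also ended calls in the response of control cells for chromatin 0.15 and macrophage identity 0.26, and in the response of diabetic cells for oxidative phosphorylation 0.17, chromatin 0.096 and macrophage identity 0.059. It also ended calls in the interaction for chemokines 0.15, type I interferon 0.18, M1-type 0.19, inflammasome 0.37, glycolysis 0.72 and NRF2 0.31, and in the mean of both states for chemokines 0.37, GTPases 0.069, fatty acid oxidation 0.086, cholesterol 0.18 and cell cycle 0.069. Leaving out control mouse 3 gave new calls in the response of diabetic cells for mitochondrially encoded 0.035, and in the mean of both states for cytokines 0.045 and TCA cycle 0.047.

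The use of median-of-ratios scaling ended calls between phenotypes in stimulated cells for fatty acid oxidation 0.13 and insulin 0.14, and in the interaction for glycolysis 0.083. It also ended calls in the mean of both states for fatty acid oxidation 0.058, cholesterol 0.075 and insulin 0.075. The use of median-of-ratios scaling gave new calls between phenotypes in stimulated cells for lipid handling 0.0090, chromatin 0.019 and ribosomal proteins 0.033, and in the response of control cells for NRF2 8.4e-06. It also gave calls in the interaction for cholesterol 0.031, and in the mean of both states for cytokines 0.040, M1-type 0.046, lipid handling 0.040, chromatin 0.043 and ribosomal proteins 0.021. The use of median-of-ratios scaling turned the direction in the response of control cells for lipid handling 8.4e-08, unfolded protein 0.0051, chromatin 1.4e-08, macrophage identity 1.6e-05, ribosomal proteins 2.0e-06 and mitochondrially encoded 3.0e-06, and in the response of diabetic cells for lipid handling 6.1e-06, unfolded protein 0.015, chromatin 1.1e-06, macrophage identity 6.6e-05, ribosomal proteins 1.4e-05 and mitochondrially encoded 0.0048. The use of quantile normalization ended calls between phenotypes in stimulated cells for type I interferon 0.16, NF-kB inhibitors 0.051, fatty acid oxidation 0.065 and macrophage identity 0.065, and in the interaction for inflammasome 0.076. The use of quantile normalization gave new calls between phenotypes in unstimulated cells for TCA cycle 0.039, fatty acid oxidation 0.039, NADPH oxidase 0.019 and insulin 0.016, and between phenotypes in stimulated cells for M1-type 0.042 and NADPH oxidase 0.00081. It also gave calls in the response of control cells for lipid handling 1.2e-15 and mitochondrially encoded 5.0e-13, and in the response of diabetic cells for lipid handling 3.0e-15 and mitochondrially encoded 1.8e-13. It also gave calls in the interaction for cytokines 0.013, GTPases 0.012, cholesterol 0.013 and macrophage identity 0.034, and in the mean of both states for MHC II 0.048, TCA cycle 0.032 and NADPH oxidase 8.5e-05. The use of quantile normalization turned the direction in the response of control cells for oxidative phosphorylation 0.00064 and NRF2 1.7e-06, and in the response of diabetic cells for oxidative phosphorylation 0.0019 and NRF2 0.16. It also turned it in the interaction for NF-kB inhibitors 0.034. The use of scaling by total reads ended calls in the response of control cells for MHC II 0.081 and hypoxia 0.18. The use of scaling by total reads gave new calls between phenotypes in stimulated cells for M1-type 0.018, TCA cycle 0.00033, unfolded protein 0.010 and NADPH oxidase 0.00090, and in the response of control cells for lipid handling 1.2e-16 and mitochondrially encoded 5.0e-10. It also gave calls in the response of diabetic cells for lipid handling 6.1e-16 and mitochondrially encoded 1.7e-10, and in the interaction for cytokines 0.016, GTPases 0.033, fatty acid oxidation 0.035 and insulin 0.033. It also gave calls in the mean of both states for MHC II 0.016, TCA cycle 0.0048 and NADPH oxidase 0.00012. The use of scaling by total reads turned the direction between phenotypes in stimulated cells for oxidative phosphorylation 0.016, chromatin 0.021, immediate early 0.032 and ribosomal proteins 0.021, and in the response of control cells for oxidative phosphorylation 1.0e-13 and NRF2 1.7e-09. It also turned it in the response of diabetic cells for M2-type 2.6e-05, oxidative phosphorylation 1.3e-12 and NRF2 0.0029, and in the mean of both states for chromatin 0.026.

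For the markers of other cells and the sex check genes, camera and an estimated correlation ended calls between phenotypes in unstimulated cells for neutrophil 0.11, progenitor 0.29, B lineage 0.57 and osteoclast 0.29, and in stimulated cells for neutrophil 0.78, progenitor 0.93, dendritic 0.93, endothelial 0.58 and osteoclast 0.88. In the responses it ended those of neutrophil 0.22, progenitor 0.76, B lineage 0.48, dendritic 0.13, endothelial 0.17 and osteoclast 0.97 in control and 0.26, 0.80, 0.41, 0.11, 0.18 and 0.97 in diabetic cells. In the mean of both states it ended neutrophil 0.41, progenitor 0.64, B lineage 0.78, endothelial 0.54 and osteoclast 0.64. Calls between phenotypes were lost within column block 1 for progenitor 0.20 and osteoclast 0.098 unstimulated, progenitor 0.57, dendritic 0.14 and osteoclast 0.083 stimulated, and progenitor 0.20, B lineage 0.21, endothelial 0.079 and osteoclast 0.13 in the mean. They were lost within column block 2 for B lineage 0.30 and osteoclast 0.057 unstimulated, dendritic 0.12, endothelial 0.054 and osteoclast 0.052 stimulated, and B lineage 0.18, endothelial 0.099 and osteoclast 0.070 in the mean. In the responses osteoclast lost its call within column block 2 (0.071 and 0.12 in control and diabetic cells), with median-of-ratios scaling (0.19 and 0.14) and with quantile normalization (0.78 and 0.33). Between phenotypes, median-of-ratios scaling ended progenitor 0.098 and dendritic 0.084 stimulated and B lineage 0.058 in the mean, and quantile normalization ended dendritic 0.45 stimulated and B lineage 0.093 in the mean. The results without control mouse 3 lost progenitor 0.11 stimulated and B lineage 0.062 in the mean. New calls were neutrophil in the interaction with median-of-ratios scaling (0.045) and quantile normalization (0.034), dendritic in the mean with scaling by total reads (0.028), and sex check genes in the responses of control and diabetic cells with scaling by total reads (1.7e-05 and 4.5e-05) and without control mouse 3 (0.0028 and 0.0025), and of diabetic cells within column block 1 (0.032).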

Other observations

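The tests within column blocks, with median-of-ratios scaling, with quantile normalization and without control mouse 3 were chosen only after the result was seen. Receptor and signalling genes were lower in diabetic cells: of 22 TLR and interferon receptors and adaptors 10 fell and 2 rose in unstimulated cells (fry adjusted p = 0.00047; adjusted p = 0.22 with an estimated correlation), and 13 fell and 4 rose in stimulated cells (fry adjusted p = 3.8e-05; adjusted p = 0.40 with an estimated correlation), with the same counts adjusted over the list alone. Within column block 2 the unstimulated list was not called (fry adjusted p = 0.057). Tlr3, a receptor for double-stranded RNA, was at 381 ± 63.3 CPM in control and 167 ± 29.5 CPM in diabetic stimulated libraries (-1.19 ± 0.11, adjusted p = 2.3e-08). Of 18 genes listed as inhibitors of NF-kB and TLR signalling 8 fell and 1 rose in unstimulated cells (10 and 1 adjusted over the list alone). The fry adjusted p was 0.00038, and 0.22 with an estimated correlation. Of 9 MHC class II presentation genes 6 rose and 2 fell in stimulated cells over all genes and over the list alone (fry adjusted p = 0.014; adjusted p = 0.88 with an estimated correlation), including H2-DMb1 (0.58 ± 0.06, adjusted p = 7.4e-09), and the list was not called in either column block (0.18 and 0.12). The interferon regulator Irf8 was at 3628 ± 302 and 2100 ± 254 CPM in stimulated libraries (-0.79 ± 0.06, adjusted p = 4.3e-10), and of the 20 interferon-gamma-induced genes of its list 12 fell and 1 rose (13 and 1 adjusted over the list alone; fry adjusted p = 0.00043; adjusted p = 0.58 with an estimated correlation), with a fry adjusted p = 0.084 within column block 2.

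Of 18 fatty acid oxidation genes 9 rose and 2 fell in stimulated diabetic cells (9 and 3 adjusted over the list alone; fry adjusted p = 0.0029; adjusted p = 0.88 with an estimated correlation). Of 13 insulin and growth factor signalling genes 5 rose and 2 fell over all genes and over the list alone (fry adjusted p = 0.00088; adjusted p = 0.88 with an estimated correlation). Both calls were lost with median-of-ratios scaling (fry adjusted p = 0.13 and 0.14). The first was also lost within column block 2 (fry adjusted p = 0.15) and with quantile normalization (0.065), and the second within column block 1 (fry adjusted p = 0.058). In stimulated cells the lists of neutrophil (fry adjusted p = 0.00011), progenitor (0.034), dendritic (0.019) and osteoclast (0.0099) markers were higher in diabetic libraries and that of endothelial markers lower (0.0016), with adjusted p = 0.78, 0.93, 0.93, 0.88 and 0.58 with an estimated correlation. Of 4 neutrophil markers 1 rose (3 adjusted over the list alone). Over all genes and over the list alone 1 of 3 progenitor markers rose, 2 of 6 dendritic markers rose and 1 fell, and 1 of 3 endothelial markers fell. Of 7 osteoclast markers 4 rose (4 rose and 1 fell adjusted over the list alone). Within column block 1 progenitor (fry adjusted p = 0.57), dendritic (0.14) and osteoclast markers (0.083) were not called, and within column block 2 dendritic (0.12), endothelial (0.054) and osteoclast markers (0.052) were not. The progenitor call was also lost with median-of-ratios scaling (0.098) and without control mouse 3 (0.11), and the dendritic call with median-of-ratios scaling (0.084) and quantile normalization (0.45). The B lineage list was not called (fry adjusted p = 0.30), nor were dendritic (0.61) and endothelial markers (0.13) in unstimulated cells. The TCA cycle (fry adjusted p = 0.32 and 0.059 in unstimulated and stimulated cells), lipid handling (0.25 and 0.097), the unfolded protein response (0.44 and 0.75), NADPH oxidase and nitric oxide (0.44 and 0.93), immediate early genes (0.61 and 0.80), ribosomal proteins (0.24 and 0.76) and the sex check genes (0.61 and 0.56) were not called between phenotypes.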
